A study of Mus musculus with 2 samples.

How the data were processed

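Single cells from mouse small intestine were profiled by droplet-based 10x Genomics RNA sequencing, in 1 library labelled control and 1 labelled model. Per the labels' protocols, mesentery and Peyer's patches were taken off, the gut was rinsed, and the tissue was digested with EDTA and then with collagenase and DNase before library construction and sequencing on an Illumina instrument. The labels do not say what was done to the animal of the model library, how many animals each library holds, or which stretch of intestine was taken.

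The deposited matrices hold whole-number counts of unique molecular identifiers (UMIs, tags that mark single captured RNA molecules) per gene and barcode, not normalised, per the file headers. Counting was done with Cell Ranger 7.0.1 per the file headers, whereas the submitters' processing notes name Cell Ranger 4.0 and the GRCm39 genome build. The gene annotation and the treatment of intronic reads are not given in the sources used here. No coordinates are printed, because no GRCm39 annotation was used here.

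The control library held 10259 barcodes and 61370270 UMIs, and the model library 11468 barcodes and 76701215 UMIs, over 56980 genes. Barcodes with at least 500 UMIs, at least 200 genes and at most 25% mitochondrial UMIs were kept, which left 7329 control and 7913 model cells. Scrublet, run within each library, called 0 of these cells doublets in either library. At a rate of 0 over this many cells the caller did not work, so no doublets were removed, and an alternative without the 8% of cells with the highest Scrublet scores was added after the data were seen.

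Cells were scaled to 10000 UMIs and log-transformed in scanpy 1.11.5 with anndata 0.12.19. The 2000 most variable genes without immunoglobulin, T cell receptor variable, mitochondrial and ribosomal protein genes gave 30 principal components, a graph of 15 neighbours and Leiden clusters at resolution 1 (igraph 0.11.9, scikit-learn 1.9.0). Both libraries were clustered together without batch correction, because library and group are the same. This gave 29 clusters, of which 25 were named from markers fixed before the data were examined and 4 stayed unnamed. A name needed at least 3 markers at 2-fold or more over the other cells and seen in at least 10% of the cluster's cells. A cluster with a median UMI count under its library's divided by 3 and no own marker among its 10 leading genes stayed unnamed. A whole class was split into its clusters, and not formed, if any of its clusters had more markers of another class than its own among those 10 genes. Names are written with "-like", since they rest on transcripts alone. T, NK and innate lymphoid cells were clustered again in the same way.

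With 1 library per group no test was possible, and no difference below has a replicate check. Shares of cells carry exact Clopper-Pearson 95% intervals. UMIs were summed per library and class and scaled to the class total as CPM (counts per mega-UMI), with exact Poisson intervals in the tables and an exact binomial interval for the model over control ratio. All intervals cover counting error only, not differences between animals or preparations. A gene at 0 in a library was set against 3 UMIs there.

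Genes were named by a size rule fixed before the data were examined, in classes with at least 100 cells in each library. Eligible genes had at least 50 UMIs in the higher library, reached 0.2 of their highest pooled CPM in any named class, and were not variable segments, mitochondrial, ribosomal protein or unnamed-locus genes. They were ranked by the interval bound nearest to a ratio of 1. The 10 highest and 10 lowest were taken in the 4 classes with the most cells, and 3 of each in other classes; a few genes that this rule or the lists took are not given. A gene list was summarised as the median log2 ratio of its members with at least 20 UMIs, with the order-statistic 95% interval and the median's percentile among 10000 random lists matched on level. The percentile describes these libraries and is no p-value. A member counted as higher or lower at a ratio of at least 1.5, or its inverse, with an interval excluding 1. After the data were seen, lists were described only in classes where at least 50% of the measured members reached 0.2 of their highest level in any class, as a guard against free RNA; single members given as highest or lowest were not held to that level. Of 39 fixed lists, the p53, type I interferon and NF-kB lists were then followed wherever they met that rule, and other lists where the median lay outside the central 95% of random lists with an interval excluding 0. The sex-linked list is given as UMIs. The distal intestine, immunoglobulin, anti-inflammatory and antimicrobial lists are given in addition, as are, after the data were seen, ribosomal proteins in enterocytes, absorptive and proximal lists in goblet cells and heat shock in macrophages; the antimicrobial list met the rule in none of the compared classes, and its value is given with the tests.

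The ratio intervals and list medians were tested on simulated data drawn from cells with a CD3 transcript, with 200 genes changed. Each gene's total was drawn as a Poisson count, which is what the intervals assume. Coverage near 95% was therefore built in and checks the calculation only. Clustering of a gene's UMIs in few cells was not simulated, so the intervals can be too narrow for such genes. The interval held the true ratio for 95.5% of 11241 unchanged genes, for 90.3% of 62 genes changed 1.5-fold, 91.2% of 80 changed 2-fold and 94.8% of 58 changed 4-fold. A list of 25 genes raised by 1 on the log2 scale came back with a median of 0.97.

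Alternatives fixed before the data were examined changed the mitochondrial limit, the depth limits, the Leiden resolution, the denominators, the way classes were named, the scaling, the weighting of cells, thinning of each cell to 1000 UMIs, removal of 5% of UMIs as free RNA, and the UMI minimum of list members. Gene ratios without the 3 cells of each library with most of the gene's UMIs, and gene and list values in the largest cluster of a class alone, were added after the data were seen. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.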

Results

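Droplet RNA sequencing measured the transcripts of single cells from mouse small intestine in 1 control library and 1 library labelled model. The series title ties the work to intestinal immune disorder under simulated microgravity and radiation and to a compound named CB001; no library labelled with the compound is analysed here. The kept cells had a median of 3636 UMIs and 1449 genes in the control library and of 3761 UMIs and 1504 genes in the model library. Their median mitochondrial share was 10.8% in the control and 5.38% in the model library. The Y-linked genes Ddx3y (3632 and 4347 UMIs in control and model), Uty (1509 and 1673), Eif2s3y (2578 and 3251) and Kdm5d (1138 and 1408) were plentiful in both libraries. Xist had 23 and 27 UMIs and its antisense gene Tsix 24 and 40. Each group holds 1 library, so every difference below is between 2 libraries and has no replicate check.

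The first comparison asked which cell classes made up each library. T cell-like cells were 18.5% of control cells (95% interval 17.6 to 19.4) and 31.5% of model cells (30.4 to 32.5). B cell-like cells numbered 4 of 7329 in the control library (0.0546%, 0.0149 to 0.140) and 277 of 7913 in the model library (3.50%, 3.11 to 3.93). Enterocyte-like cells, the absorptive cells of the villus, were 24.7% of control (23.7 to 25.7) and a smaller share of model cells (1266 of 7913, interval 15.2 to 16.8%). Paneth-like cells, the antimicrobial cells of the crypt base, were 1.15% of control (0.915 to 1.42) and 0.101% of model cells (0.0437 to 0.199). Their log2 ratio was −3.50, and −2.34 with each library clustered alone. With no mitochondrial limit it was −5.06, where the class took in a low-RNA cluster described below. Fibroblast-like cells were 1.54% of control (1.27 to 1.85) and 0.670% of model cells (0.502 to 0.875). The B cell-like and Paneth-like clusters came almost wholly from 1 library each, so their shares may reflect that library alone. They passed 10 of 10 and 8 of 8 markers of their type. With each cell named by its own marker score, B cell-like cells numbered 4 and 252 and Paneth-like cells 102 and 14 in control and model.

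Enteroendocrine-like cells were 1.15% of control (0.915 to 1.42) and 1.92% of model cells (1.63 to 2.25). Plasma cell-like cells were 6.73% of control (6.16 to 7.32) and 8.43% of model cells (7.83 to 9.06). This order turned around with a mitochondrial limit of 10% and as a share of the named immune classes. NK or innate lymphoid-like cells were 0.505% (0.356 to 0.695) and 0.796% (0.612 to 1.02), plasmacytoid dendritic cell-like cells 0.641% (0.472 to 0.852) and 0.329% (0.215 to 0.481), and enteric glia-like cells 20 and 6 cells. For crypt stem or transit-amplifying-like, goblet-like, macrophage or monocyte-like, dendritic cell-like, tuft-like, endothelial, smooth muscle or pericyte-like and mesothelial cells the interval of the model over control ratio included 1. An unnamed cluster of low-RNA cells (median 821 UMIs) held 16.4% of control cells (15.6 to 17.3) and 0.379% of model cells (0.256 to 0.541), which lowers every other control share. Of the other unnamed clusters, cluster 4, led by Lars2 and low in RNA, held 4.09% and 9.65%, cluster 5, led by cell cycle genes, 5.09% and 6.19%, and cluster 6, led by Car4, 1.92% and 3.77% of control and model cells. Unnamed clusters together held 27.5% of control (26.5 to 28.6) and 20.0% of model cells (19.1 to 20.9). At a mitochondrial limit of 10% the log2 ratio of the enterocyte share went from −0.63 to −0.015, of the enteroendocrine share from 0.75 to 0.11 and of the fibroblast share from −1.20 to −1.84. Classes whose interval included 1 moved too: goblet cells from −0.19 to −0.75, macrophages from −0.21 to −0.82 and crypt cells from 0.17 to −0.22. Within the named epithelial classes the crypt ratio was 0.56. Within the named immune classes the T cell ratio went from 0.77 to 0.11. Under 4 alternatives the T cell class was not formed, for which any failing cluster is enough.

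**Figure D1:**
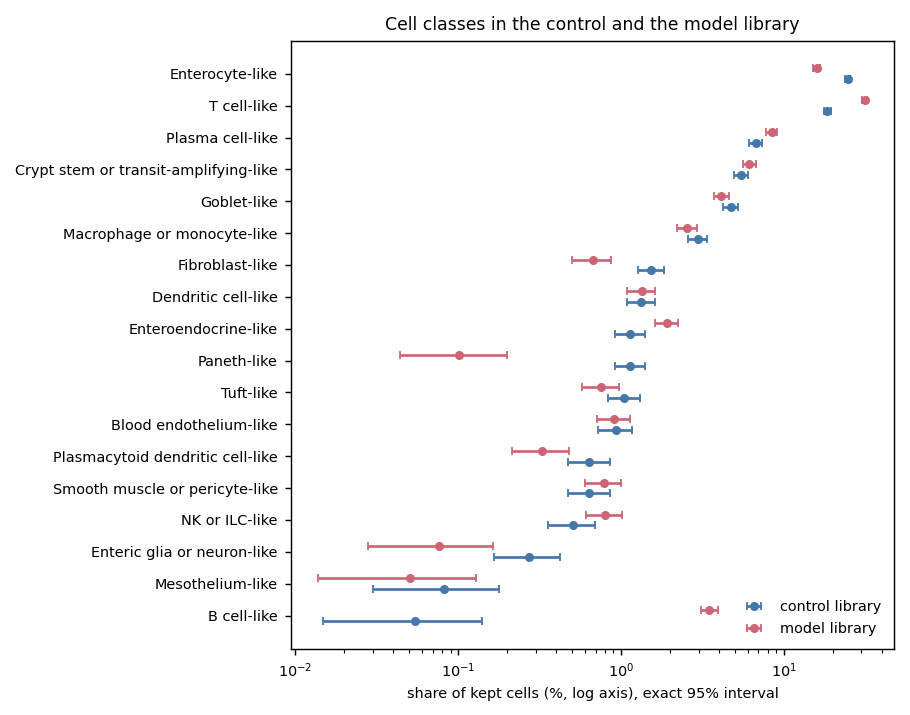
Share of kept cells in each named class (percent, log axis) in the control and the model library, with exact 95% intervals that cover counting error only. T cell-like cells stand at 18.5% and 31.5%, B cell-like cells at 0.0546% and 3.50%, and Paneth-like cells at 1.15% and 0.101%.

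Enterocyte-like cells (1810 control and 1266 model cells) were compared for gene levels. Duox2, a hydrogen peroxide-producing oxidase, had 1304 control and 33 model UMIs (47.0-fold lower, 33.3 to 68.6), its maturation factor Duoxa2 1139 and 33 (41.1-fold, 29.1 to 60.0), and Nos2, the inducible nitric oxide synthase, 856 and 41 (24.9-fold, 18.2 to 34.9). Saa1, an acute-phase protein, had 116 control and 0 model UMIs, at least 46.0-fold lower. Also lower were Adcy8 (113-fold, 19.8 to 4513), Fam151a (32.7-fold), Tmigd1 (28.3-fold) and the monocarboxylate carrier gene Slc5a8 (23.1-fold).

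Genes with higher levels in the model enterocytes included the clock output factor Dbp (33 and 286 UMIs, ratio 7.28, 5.07 to 10.8), the duodenal transcription factor Pdx1 (7 and 63, ratio 7.56, 3.46 to 19.6) and the nuclear receptor Nr0b2 (9 and 77, ratio 7.19, 3.60 to 16.3). Cyp1a1, a target of the aryl hydrocarbon receptor, had a ratio of 4.70 (4.09 to 5.42) and the cytokine gene Il18 of 2.86 (2.70 to 3.02). Fer1l4 (5.51), Adh4 (3.62), Akr1c19 (3.31) and Car4 (3.05) were also higher.

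Among gene groups in enterocytes, the oxidative stress and NRF2 list had a median log2 ratio of 0.66 (0.18 to 0.84; percentile 99.98), with 13 of 24 members higher and 0 lower. The glutathione transferases Gsta4 (ratio 3.06, 2.64 to 3.55) and Gsta1 (2.62, 2.48 to 2.76) were highest, and Srxn1 (0.784) and Hmox1 (0.735, 0.332 to 1.61) lowest. Nuclear genes of mitochondrial respiration had a median of 0.60 (0.46 to 0.66), with 14 of 24 higher, among them Cox5a (2.18) and Ndufb8 (1.92); Uqcrc1 (1.12) and Ndufa2 (1.10) were lowest. With a mitochondrial limit of 10% this median was 0.10. Ribosomal protein genes, 0 of 24 at their own level in enterocytes, had a median of 0.93 (0.76 to 0.97) with 24 of 24 higher. Mitochondrially encoded genes had a median of −0.45 (−0.56 to −0.14) with 2 of 13 lower. Both may be signs of the make-up of the RNA, which was not tested. Over all kept cells the median mitochondrial share was lower in the model library too (5.38%, control 10.8%), so the latter shift need not be particular to enterocytes. Villus tip genes had a median of −0.69 (−1.31 to −0.16), with 6 of 11 lower, including Nt5e (3.83-fold lower, 3.49 to 4.20) and Slc28a2 (2.48-fold, 2.34 to 2.63), while Glul (1.51) and Creb3l3 (0.897) were highest. In cluster 3 alone, the enterocyte cluster with most cells, the medians were 0.27 for NRF2, 0.22 for respiration, −0.0068 for villus tip, −0.32 for ribosomal and 0.061 for mitochondrially encoded genes, so these values also carry the make-up of the class.

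Proximal intestine genes had a median of 0.66 (0.04 to 1.18), with 7 of 13 higher; Slc40a1 (2.46) and Cyp2c29 (2.44) were highest and Apoa4 (0.844) and Lct (0.784) lowest. Distal intestine genes had a median of −0.61 (−3.92 to 0.10), with 6 of 11 lower. Tmigd1 and the bile acid carrier gene Slc10a2 (15.2-fold lower, 5.58 to 57.8) were lowest, and Slc51b (1.11) and Muc3 (1.07) highest. The type I interferon list had a median of −0.15 (−0.25 to 0.14), with Ifi27l2a (2.60) and Bst2 (2.38) highest and Irf7 (0.577) and Mx1 (0.364) lowest. The p53 list had a median of −0.01 (−0.30 to 0.44), with 4 higher and 4 lower of 27, from Polk (2.03) and Gdf15 (1.79) to Bbc3 (0.472) and Plk2 (0.361). Different clusters held most enterocytes of each library: cluster 2, led by Fabp1, Gsta1 and Papss2, had 235 control and 718 model cells, and clusters 3, led by Cubn, and 19, led by Clca4a, had 1074 and 501 control and 401 and 147 model cells. Plb1 (1416 UMIs and 1 UMI, 1686-fold lower, 302 to 66623), Slc34a2 (16.9-fold lower), Papss2 (2.93-fold higher), Gsta1, Nt5e and Slc28a2 are among the 10 genes that lead these clusters, so their ratios also carry the make-up of the class. Any other gene that differs between these clusters, Il18, Car4 and Akr1c19 included, can be moved by the make-up in the same way. The median log2 ratio over all enterocyte genes was 0.10.

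Crypt stem or transit-amplifying-like cells (402 control and 488 model cells) were compared next. Duox2 was 3.62-fold lower (3.02 to 4.36) in the model library, Duoxa2 4.04-fold (2.96 to 5.62), Nos2 2.89-fold (2.14 to 3.97) and the oxidase Nox1 2.23-fold (1.64 to 3.07). Ceacam10 (2.39-fold), Lypd8l (2.15-fold), Syne4 (2.68-fold), Mpp3 (2.71-fold), Slc14a1 (1.95-fold) and Cfi (2.27-fold) were also lower. The BMP target genes Id1 and Id3 were higher at ratios of 1.72 (1.65 to 1.80) and 1.48 (1.40 to 1.56). Akr1c13 (1.92), Akr1c12 (1.59), Ugt1a6a (2.55), Acot1 (1.81), Pbld1 (1.81), Edn2 (1.69) and Onecut2 (1.48) were also higher.

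The p53 list had a median of 0.15 in crypt cells (0.01 to 0.30; percentile 100), with 2 of 30 members higher: Phlda3 (1.71, 1.02 to 2.95) and Gdf15 (1.59, 1.31 to 1.93). Fas (0.756) and Eda2r (0.682) were lowest. Tight junction and mucus genes had a median of −0.17 (−0.28 to −0.09), with 0 of 18 members past the size limit, from Cldn3 (1.19) and Epcam (1.02) to Cldn2 (0.730) and Tff3 (0.668). Mitochondrially encoded genes had a median of −0.47 (−0.60 to −0.30; percentile 0.00), with 3 of 13 lower. Edn2 turned to a log2 ratio of −0.25 when each cell was thinned to 1000 UMIs.

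T cell-like cells (1357 control and 2490 model cells) had smaller ratios. The Ly49 receptor genes Klra7 (71 and 439 UMIs, ratio 3.79, 2.94 to 4.94; ENSMUSG00000067599) and Klra6 (47 and 184, ratio 2.40, 1.73 to 3.38) and the related receptor gene Klre1 (1.57) were higher in the model library. Klra7, Klra6 and Klre1 lead a cluster of the lymphocytes clustered again with 23 control and 195 model cells, of 1394 and 2553, so their ratios also carry its share. Also higher were Sh2d1a (2.00), Slfn1 (1.84) and Nab2 (1.82). The chemokine gene Xcl1 was 2.48-fold lower (2.30 to 2.68), the actin-severing protein gene Scin 2.94-fold (2.56 to 3.37) and Cdk5rap1 4.16-fold (2.44 to 7.37). Xcl1 leads lymphocyte cluster 12 of that clustering (86 control and 90 model cells, 6.17% and 3.53% of the lymphocytes). Scin leads cluster 1 (127 and 340 cells, 9.11% and 13.3%) and is also among the leading genes of cluster 8 (142 and 302 cells, 10.2% and 11.8%). The shares of clusters 1 and 8 were not lower in the model library, unlike Scin. H2bc11 (2.22-fold), Zmat4 (1.92-fold), Prmt3 (1.92-fold), Rnu11 (1.86-fold), Dgat1 (1.48-fold), Actb (1.34-fold) and Plec were also lower, of which Rnu11 is among the leading genes of low-RNA lymphocyte cluster 7 (204 control and 82 model cells). The size rule also named the chemokine genes Ccl3 (1.47, 1.40 to 1.54) and Ccl4 (1.44, 1.41 to 1.47), which lead T cell-like cluster 11 (284 control and 471 model cells), and Dusp2 (1.63) and Ms4a4b (1.49), which lead cluster 14 (146 and 390 cells). In cluster 10 alone, the T cell-like cluster with most cells, Ccl3, Dusp2, Ms4a4b and Sh2d1a were lower in the model library.

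The type I interferon list had a median of 0.25 (0.06 to 0.38), with 0 of 27 members past the size limit; Ifit3 (2.28, 0.962 to 6.21) and Usp18 (1.76) were highest and Oasl2 (0.844) and Stat2 (0.812) lowest. In cluster 10 alone this median was 0.015. The p53 list had a median of 0.12 (−0.02 to 0.26), from Sesn2 (1.49) and Ddb2 (1.37) to Sesn1 (0.744) and Plk2 (0.501). The NF-kB list had a median of 0.14 (−0.29 to 0.32), from Il18 (2.73) and Ccl3 to Relb (0.772) and Csf2 (0.582); it was −0.047 in cluster 10 alone. Il18 (20 and 89 UMIs) was below its own level in T cells and higher in enterocytes, so free RNA can carry it. The unfolded protein list had a median of −0.24 (−0.32 to −0.07), from Asns (1.12) and Edem1 (1.09) to Ddit3 (0.656) and Trib3 (0.613). Cholesterol synthesis genes had a median of −0.15 (−0.23 to −0.03), from Sqle (1.08) and Fdft1 (1.02) to Lss (0.694). Mitochondrially encoded genes had a median of −0.31 in T cells (−0.47 to −0.14; percentile 0.00), with 0 of 13 past the size limit.

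Among the T, NK and innate lymphoid cells clustered again, CD4 T cell-like cells were 7.39% of control (6.07 to 8.89) and 12.1% of model cells (10.8 to 13.4). NK or ILC1-like cells were 1.08% (0.603 to 1.77) and 0.392% (0.188 to 0.719), from 15 and 10 cells. ILC3-like cells were 2.51% (1.75 to 3.47) and 2.43% (1.87 to 3.10). The other clusters, 12 of 15, met no marker set and are not compared. Among them, cluster 5 (62 control and 109 model cells) was led by plasma and goblet cell genes such as Jchain and Muc2. Cluster 9 (51 and 61) was led by enterocyte genes such as Apoa1, and cluster 13 (16 and 27) held Dmbt1 of the proximal list. Low-RNA cluster 7 (204 and 82) held Defa24 and Muc2 among its leading genes. Doublets or free RNA can carry such genes. These cells stay in the denominators of these shares and, where T cell-like, in the T cell sums.

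In plasma cell-like cells (493 control and 667 model cells) no isotype differed in its share of cells beyond the counting interval, while UMIs of some heavy chains did. Ighg1 had 15 control and 905 model UMIs (ratio 45.0, 27.1 to 80.7; ENSMUSG00000076614) and Ighg3 113 and 2642 (17.4, 14.4 to 21.2), whereas Ighg2b was 3.22-fold lower (3.10 to 3.34). Ighm (1.81, 1.68 to 1.94) and Ighg2c (1.30, 1.24 to 1.37) were higher, and Igha, with 515324 and 609639 UMIs, had a ratio of 0.882. Counted by the heavy chain with the most UMIs, 97.8% of control (96.0 to 98.9) and 96.4% of model plasma cells (94.7 to 97.7) were Igha cells, and Ighg1 and Ighg3 led in 3 model cells each and in 0 of 493 control cells, which has an upper bound of 0.745%; Ighg2b led in 7 and 10 cells. Few cells carry these UMIs: the 3 model cells with most held 866 of the 905 Ighg1 and 2556 of the 2642 Ighg3 UMIs. Without the 3 highest cells of each library Ighg3 had a ratio of 1.28 (0.892 to 1.85), Ighg1 0 and 39 UMIs, and Ighg2b was 3.77-fold lower. The 9 measured members of the immunoglobulin list had a median of 0.38 (−0.26 to 4.12), with Jchain at 0.924, Mki67 at 1.73 and Fas at 0.834.

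The proliferation list had a median of 0.69 in plasma cells (0.55 to 0.79; percentile 100), with 18 of 28 members higher and 0 lower. In cluster 9 alone (460 control and 598 model cells) the median was 0.12 and Cdc20 was lower in the model library, so the value also carries the share of plasma cell-like cluster 25 (33 and 69 cells, median 13289 UMIs). Bub1 (3.54) and Tpx2 (2.91, 1.95 to 4.47) were highest and Rrm2 (1.12) and Mcm6 (1.03) lowest. By the size rule Cdkn3 (3.09), Cdc20 (2.27), Cdca3 (2.21), Hmmr (2.03), H1f5 (1.70) and H1f3 (1.67) were also among the 10 highest genes. Lower were the light chain genes Iglc2 (2.52-fold) and Iglc3 (1.35-fold), which lead cluster 9 together with Ighg2b, the metallothionein Mt2 (2.02-fold, 1.80 to 2.28), Golga3 (1.72-fold), Sgk3 (1.76-fold), Ripor2 (1.61-fold), Septin1 (1.49-fold), Dennd4a (1.37-fold) and Nmt1. With each cell thinned to 1000 UMIs the proliferation median was 0.38, and Sgk3, Ripor2 and Iglc3 turned direction. Iglc3 also did without the 3 highest cells of each library, and Iglc2 then stayed lower but by less.

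**Figure D2:**
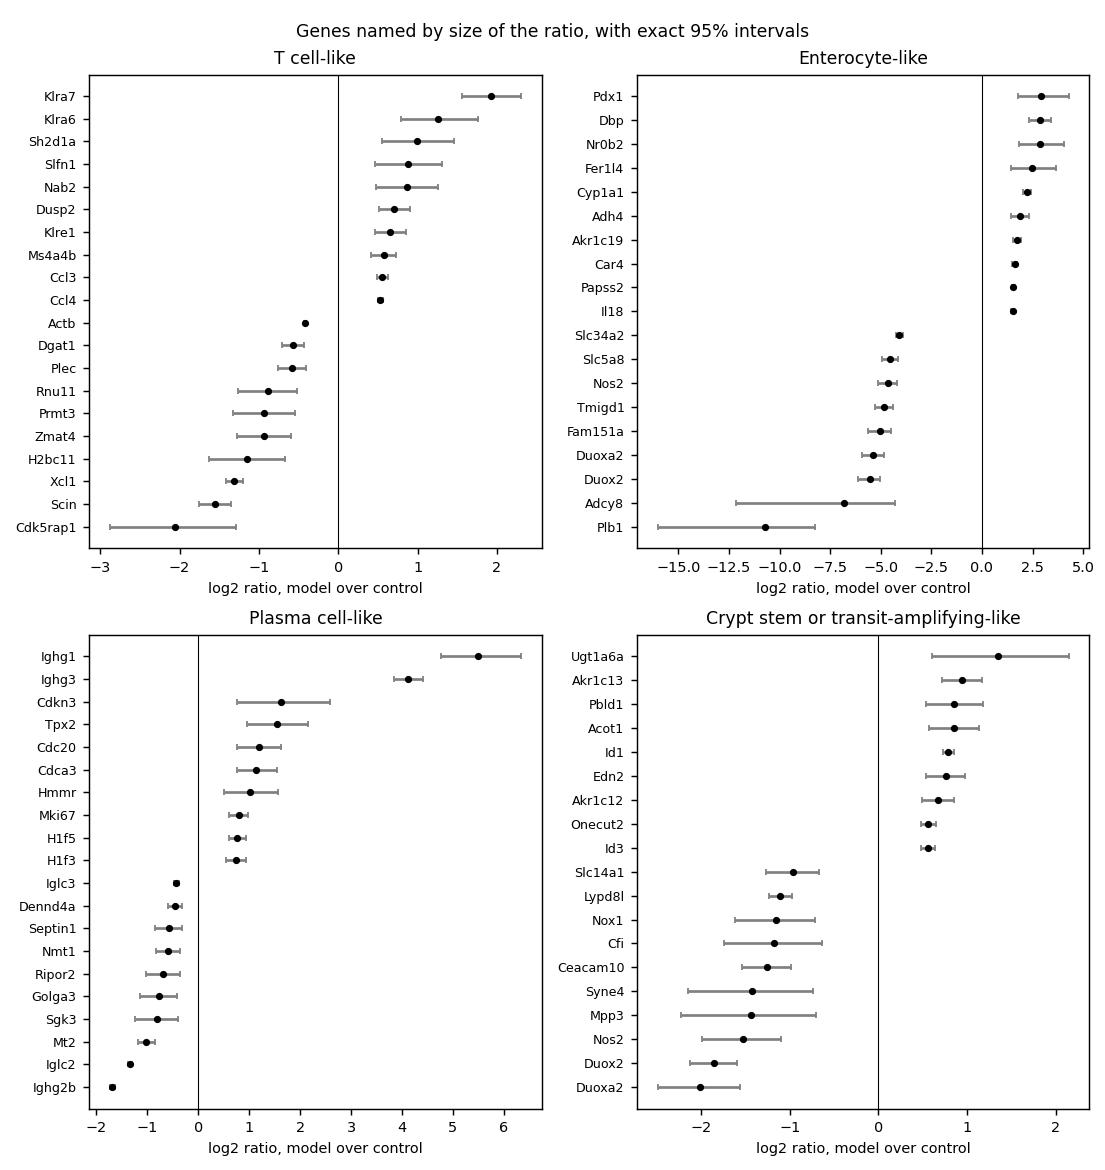
Log2 ratio of CPM, model over control, for the genes named by size and given in the text, in the 4 classes with the most cells; points are ratios and bars exact 95% intervals for counting error. Duox2, Duoxa2 and Nos2 are lower in both epithelial panels, and Saa1, at 0 UMIs in model enterocytes, has no finite ratio and is not drawn.

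Goblet-like cells (346 control and 328 model cells) had a type I interferon median of 0.60 (0.14 to 0.84; percentile 100), with 14 of 27 members higher and 0 lower. Absorptive genes were higher in the same cells: sugar and peptide digestion had a median of 1.29 (1.08 to 1.55; 17 of 18 higher, 2 at their own level), lipid absorption 1.05 (0.82 to 1.60; 16 of 19, 3 at their own level) and the proximal list 1.10 (0.07 to 2.07; 8 of 12 higher, 4 at their own level). Enterocyte RNA can therefore carry part of the goblet values. Among the interferon genes Usp18 (4.01, 1.42 to 13.9) and Trim30a (3.28, 2.01 to 5.54) were highest, and Oas1a (0.757) and Mx1 (0.674) lowest. By the size rule the highest genes were Pck1 (ratio 3.61, 3.06 to 4.27), Gstm6 (4.72, 2.86 to 8.14) and Ces1f (3.50, 2.77 to 4.47). The lowest by that rule were Duox2 (7.63-fold lower, 5.25 to 11.4), Saa1 (8.59-fold, 3.96 to 22.1) and Mgat4c (5.93-fold, 3.04 to 12.9). Proliferation genes had a median of −0.57 (−0.73 to −0.46), from Mcm6 (1.34) and Mcm2 (1.20) to Aurka (0.444) and Ccna2 (0.407), and ribosomal protein genes −0.33 (−0.40 to −0.26), with Rpl5 at 0.908, Rpl4 at 0.894 and Rpl35 at 0.722. Both medians changed sign without the cells of highest doublet score, to 0.44 and 0.17. Cholesterol synthesis genes had a median of −0.29 (−0.52 to −0.07), with Insig1 at 1.04, Fdps at 0.681 and Mvd at 0.634. The p53 median was 0.07 (−0.06 to 0.20), from Fas (1.91) and Trp53inp1 (1.47) to Ddit4 (0.633) and Gdf15 (0.433). The distal intestine list, which holds enterocyte genes as well, had a median of 0.58 (−0.41 to 0.95), from Mep1a (2.04) and Slc51a (1.93) to Osr2 (0.750) and Tmigd1 (0.205).

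Macrophage or monocyte-like cells (217 control and 203 model cells) were compared last. The NF-kB list had a median of −0.61 (−0.80 to −0.13; percentile 0.00), with 14 of 26 members lower and 3 higher: Tnfsf9 (3.73-fold lower, 1.37 to 12.6) and Il1a (2.82-fold, 1.40 to 6.16) were lowest and Ccl5 (2.64) and Cxcl10 (1.61) highest. The cytotoxicity list, a sign of lymphocyte RNA that also holds Ccl5, had a median of 1.20 in the same cells (−0.41 to 4.08; 5 of 8 higher, 0 lower, 1 at its own level), so lymphocyte RNA can carry Ccl5. The heat shock and dissociation stress list, a sign of handling, had a median of −0.28 in the same cells (−0.52 to 0.03; percentile 0.00), with 3 of 22 lower and 2 higher. By the size rule the lowest genes were Mmp12 (74 UMIs and 1 UMI, 65.6-fold lower, 11.4 to 2627), Spp1 (9.17-fold, 3.98 to 25.9) and the monocyte attractant Ccl2 (2.62-fold, 2.09 to 3.30). Il22ra2, a soluble receptor that binds interleukin 22, had 1 control and 209 model UMIs (ratio 236, 41.8 to 9351), and a log2 ratio of at least 4.12 without the 3 highest cells of each library; Chil3 (8.76) and Ccl24 (6.40, 5.10 to 8.11) were also higher.

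Anti-inflammatory genes had a median of −0.57 (−0.69 to 0.10), with 6 of 13 macrophage members lower, from Lag3 (1.83) and Tsc22d3 (1.20) to Il10 (1.73-fold lower, 1.29 to 2.36) and Ctla4 (3.02-fold). Resident macrophage genes had a median of −0.35 (−0.45 to −0.10), from Mertk (1.30) and C1qb (1.13) to Mrc1 (0.626) and Lyve1 (0.417). The unfolded protein list had a median of −0.35 (−0.54 to −0.24), from Pdia6 (0.928) and Xbp1 (0.880) to Creld2 (0.542) and Ddit3 (0.364); thinned to 1000 UMIs per cell it was −0.17. Respiration genes had a median of 0.33 (0.10 to 0.46), from Cox5a (2.07) and Ndufv2 (1.99) to Ndufa2 (0.932) and Uqcrc1 (0.881). The type I interferon median was 0.25 (0.04 to 0.57), from Usp18 (2.37) and Oas1a (2.14) to Oas3 (0.820) and Ifit3 (0.689), but 0.019 with means over cells. The p53 median was 0.09 (−0.19 to 0.73), from Ddit4 (7.61) and Bax (2.37) to Trp53inp1 (0.511) and Plk2 (0.399), and −0.24 with thinned cells. The villus tip list had a median of −0.35 (−0.62 to −0.02), from Slc28a2 (1.05) and Neat1 (0.989) to Nt5e (0.653) and Ada (0.630); 5 of these 10 members reached 0.2 of their highest level in any class.

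**Figure D3:**
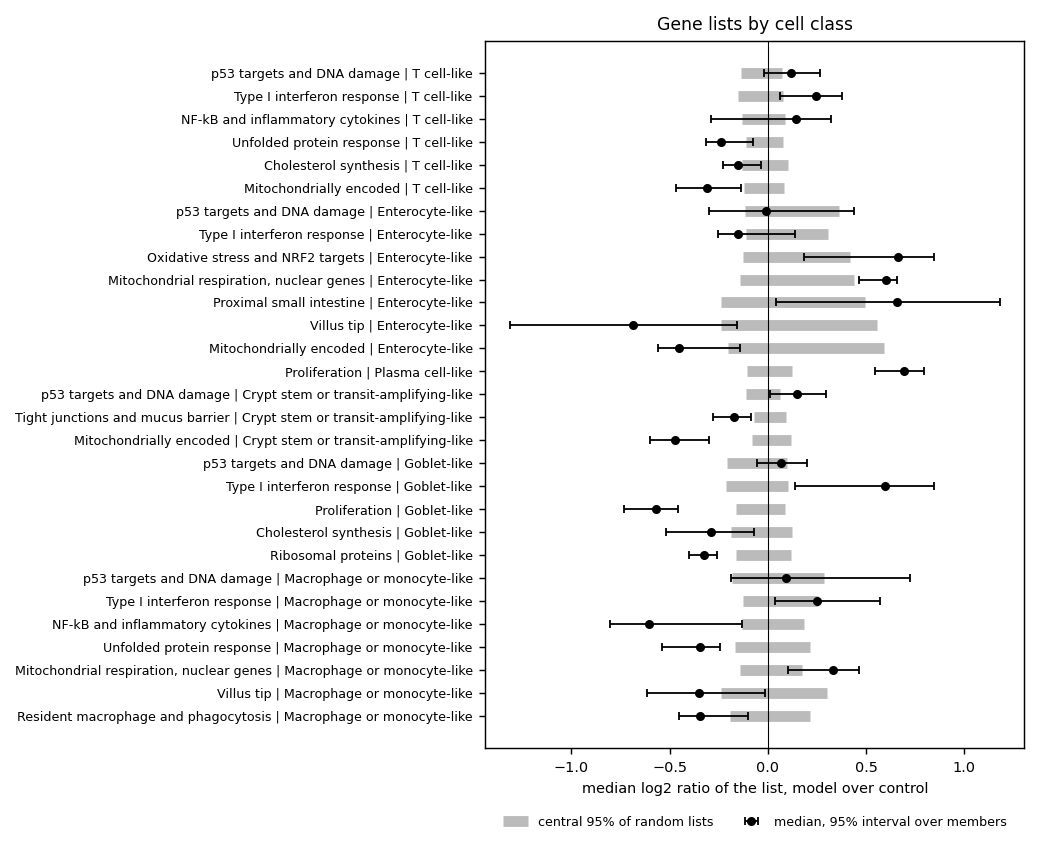
Median log2 ratio, model over control, of the gene lists followed in each class, with the 95% interval over members; grey bars are the central 95% of random lists matched on level. The NF-kB list in macrophages lies at −0.61 and the proliferation list in plasma cells at 0.69, both outside their grey bars.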

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

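Results outside the main comparisons are given first, then a pattern weighed. Of the tests below, the UMI test of doublets, the range over resampled genes and the name without a mitochondrial limit were chosen only after the result was seen.

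Barcodes outside the cell filters made up 31.0% of the model library (30.2 to 31.9) and 28.6% of the control library (27.7 to 29.4); they enter none of the main comparisons, and those over the mitochondrial limit only the alternative without it; they are listed because the model share is the higher. The unnamed low-RNA cluster 4 held 9.65% of kept model cells (9.01 to 10.3) and 4.09% of kept control cells (3.65 to 4.57), and its cells enter no named class.

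A further low-RNA cluster held 16.4% of control and 0.379% of model cells. Doublets of the library's other cells are argued against by its UMIs: only 5 of its 1205 control cells (0.415%, 0.135 to 0.966) held at least the median of 4394.5 UMIs of the other control cells. Removal of the model share by the mitochondrial limit was weighed only in the cluster that took most of these cells without it. That cluster, holding 1123 of these 1205 cells, was still 38.6-fold more common in the control library (27.5 to 56.0). It then took the name Paneth and made up 1177 of 1260 control and 34 of 42 model cells of that class. Model cells over the limit that joined other clusters were not followed, so the limit stays possible for those. Without the limit, enterocyte-like cells went from 1810 to 3115 in the control and from 1266 to 3127 in the model library. Enterocytes that lost RNA stay possible but were not singled out by the rank correlation across genes. It was 0.749 with the enterocyte class, 0.757 with the goblet class and 0.727 with the Paneth class. The gap of the first to the goblet class was −0.0085, with a range over resampled genes of −0.021 to 0.0058. Looked at afterwards, the cluster's 10 leading genes held Ada (villus tip list) and Slc27a4 (lipid absorption list) beside mitochondrially encoded genes. With each cell named by its own marker score, control enterocyte-like cells went from 1810 to 3519, goblet-like from 346 to 563 and Paneth-like from 84 to 102. Model enterocyte-like cells went from 1266 to 2649, and these counts also take in other unnamed clusters, so they do not settle it. A cell state of the control animal or a handling difference cannot be told apart with 1 library per group.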

How the results depend on the processing

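No paired analysis was possible because each group holds 1 library. Doublets kept gives the main values, since Scrublet called 0 cells, so it tests nothing. Removal of the 8% of cells with the highest Scrublet scores, shares of the cells in named classes, list members at their own level, removal of the 3 cells of each library with most UMIs of a gene, and the cluster of a class with most cells alone (T, enterocyte and plasma cells) were alternatives chosen after seeing the data. Turned means that the sign changed where the main interval excluded 0. Values are log2 ratios, and the cause was not tested for any change below. Thinning left out cells with under 1000 UMIs, from 1 control crypt cell to 167 model T cells per class and library.

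Of the alternative values for 11 class shares, 75 stayed within the counting interval, 24 moved beyond it and 2 turned; in all, 8 changed sign, the others from main intervals that included 0. At a mitochondrial limit of 10% the shares were −0.23 for plasma cells (turned), −0.22 for crypt, −0.015 for enterocytes, 0.11 for enteroendocrine cells, −1.84 for fibroblasts, −0.75 for goblet cells, −0.82 for macrophages and 0.32 for T cells. With no mitochondrial limit they were −0.15 for enterocytes and −5.06 for Paneth cells, a class of 1260 control and 42 model cells that then takes in the low-RNA cluster (1177 and 34 cells). With at least 1000 UMIs and 500 genes the enterocyte share was −0.74. Naming each cell by its own marker score gave 0.67 for dendritic cells, −0.52 for enterocytes and −0.56 for goblet cells. Each library clustered alone gave 0.42 for crypt, 0.38 for macrophages and −2.34 for Paneth cells. Within the compartment the shares were −0.33 for plasma cells (turned), 0.56 for crypt, −0.65 for dendritic cells, −0.23 for enterocytes, 0.21 for goblet cells, −0.86 for macrophages and 0.11 for T cells. Compartments held named classes only. The unnamed clusters, 27.5% of control and 20.0% of model cells, were left out of these denominators, so the values can depend on that. Among named classes they were −0.77 for enterocytes and 0.62 for T cells. Of 7 alternative values for 3 lymphocyte shares, 6 stayed within the interval, and at Leiden resolution 2 the CD4 T cell share was 0.35.

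The T cell class was not formed with at least 1000 UMIs and 500 genes, without the highest Scrublet scores, at Leiden resolution 2, or with each library clustered alone. Any failing cluster drops a whole class, so this need not mean that T cells were not recognised. The dendritic cell class could not be named at Leiden resolution 0.5 or in the model library alone, nor plasma cells in the model library alone or B cells in the control library alone; these give no values.

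Of 495 alternative values for 38 list medians, 444 stayed within the interval, 47 moved beyond it and 4 turned; in all, 17 changed sign, and moves of lists given in addition are not printed. Without the highest Scrublet scores the goblet medians were 0.44 for proliferation and 0.17 for ribosomal proteins (both turned) and 0.23 for p53, the macrophage unfolded protein median was −0.23 and the crypt median of mitochondrially encoded genes −0.61. Thinning gave −0.33 for cholesterol synthesis and −0.48 for mitochondrially encoded genes in T cells, 0.94 for NRF2 and 0.85 for respiration in enterocytes, 0.38 for proliferation in plasma cells, 0.23 for p53, −0.037 for proliferation and −0.067 for ribosomal proteins in goblet cells, and −0.24 for p53 and −0.17 for unfolded protein in macrophages. Means over cells gave −0.28 for cholesterol synthesis in T cells, 0.90 for respiration in enterocytes, 0.53 for proliferation in plasma cells, −0.15 for proliferation and −0.046 for ribosomal proteins in goblet cells, and 0.019 for interferon in macrophages. Own marker scores gave −0.31 for interferon, 0.36 for respiration and −0.60 for mitochondrially encoded genes in enterocytes, 0.36 for proliferation in plasma cells, and −0.24 for proliferation and −0.15 for ribosomal proteins in goblet cells. Deeper cells gave −0.38 for proliferation and −0.23 for ribosomal proteins in goblet cells. A mitochondrial limit of 10% gave 0.10 for respiration in enterocytes, and no limit −0.35 for proliferation in goblet cells. The cluster with most cells alone gave 0.015 for interferon and −0.32 for unfolded protein in T cells, 0.22 for respiration, −0.0068 for villus tip, −0.32 for ribosomal proteins (turned) and 0.061 for mitochondrially encoded genes (turned) in enterocytes, and 0.12 for proliferation in plasma cells.

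Of 997 alternative values for 92 genes, 832 stayed within the interval, 154 moved beyond it and 11 turned. Thinning gave 0.29 for Sgk3, 0.16 for Iglc3 and 0.035 for Ripor2 in plasma cells and −0.25 for Edn2 in crypt cells, and means over cells gave 0.21 for Iglc3. Without the 3 highest cells of each library Iglc3 was 0.080 (turned), Ighg1 at least 3.27, Ighg3 0.35 and Iglc2 −0.53 in plasma cells, Xcl1 −0.86 in T cells and Il22ra2 at least 4.12 in macrophages. The cluster with most cells alone gave −0.12 for Sh2d1a, −0.39 for Dusp2, −0.19 for Ccl3 and −0.75 for Ms4a4b in T cells and −0.33 for Cdc20 in plasma cells, all turned. The median over all enterocyte genes was 0.10, and between −0.03 at the lower mitochondrial limit and 0.17 for means over cells.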

Other observations

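The genes in this paragraph were chosen after their values were seen, and the antimicrobial list, haemoglobin (also without its highest cells) and naive T cell tests were chosen only after the result was seen. The naive T cell rule was made stricter after its value was seen, and the tests within enterocyte clusters took the place of a test in crypt cells whose result had been seen. In enteroendocrine-like cells (84 control and 152 model cells) Pyy, a hormone of distal gut endocrine cells, had 2379 control and 73 model UMIs (44.5-fold lower, 35.2 to 56.9), and Calcb had 0 and 66 UMIs, at least 16.1-fold higher. Of the 6 hormone genes among those leading this cluster, Gip, a proximal hormone, was lower as well (16381 and 13583 UMIs, 1.65-fold, 1.61 to 1.68). So were Nts (2.89-fold, 2.77 to 3.02), Ghrl (1.40-fold, 1.35 to 1.45) and Sct (1.38-fold, 1.34 to 1.41), while Cck (ratio 1.61, 1.58 to 1.64) and Gcg (1.88, 1.77 to 2.00) were higher. In fibroblast-like cells the fat-cell genes Car3 (1198 and 0 UMIs, at least 135-fold lower), Adipoq (100 and 0, at least 11.3-fold lower) and Fabp4 (2582 UMIs and 1 UMI) belonged to the control library. In endothelial cells Selp had 356 and 7 UMIs (28.7-fold lower, 13.8 to 72.0). The mucosal mast cell proteases Mcpt1 (6 and 150 UMIs) and Mcpt2 (1 and 107) were higher in the dendritic cell-like cluster of the model library, but over all kept cells the ratios were only 1.86 (69 and 160 UMIs, 1.39 to 2.50) and 2.07 (44 and 114, 1.45 to 3.01). In that cluster Il22ra2 had a ratio of 2.31 (1.71 to 3.15).

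Sampling of a different stretch of intestine may account for the lower distal and higher proximal lists in model enterocytes, but the tests leave it open. The difference of the list medians was 1.04 and 1.10 in enterocyte clusters 3 and 19, above random pairs, and 0.18 in cluster 2, within them. Fabp1, Rbp2 and Slc2a2 of the proximal list are among the leading genes of cluster 2, and Cubn of the distal list of cluster 3. Cluster 2 held 235 control and 718 model cells, so such a difference can lie in the split itself. The value within cluster 2 therefore cannot weigh against it. Loss of villus tip cells as the whole cause is left open by the same clusters. In clusters 3, 19 and 2 the distal medians were −0.44, −0.69 and −0.14, against lower random bounds of −0.26, −0.33 and −0.19. Ada, Slc28a2 and Nt5e of the villus tip list are among the leading genes of cluster 19, so the split itself can carry such a loss. In crypt cells the difference was 0.85, yet only 2 of 11 distal and 3 of 12 proximal members reached their own level there, so free enterocyte RNA can carry it. A weaker microbial or cytokine drive stays open, because its test holds nothing. The antimicrobial median was −1.33 in crypt cells but also −2.73 in T cells and −2.51 in plasma cells. In T and plasma cells 0 members reached their own level, so free RNA can carry it. In enterocytes (−3.03) 13 of 18 measured members were lower and 3 higher, and in goblet cells (−0.44) 10 of 20 were lower and 2 higher. Of the measured members, 8 in each of these classes reached their own level. They went both ways, in enterocytes from Reg3b (ratio 2.37) to Duox2 (47.0-fold lower). An effect of the model itself was not tested and stays open.

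B cell-like cells numbered 4 in the control and 277 in the model library. Blood left in the model tissue with its red cells is argued against. The 4 haemoglobin genes together had a model over control ratio of 0.0221 (0.0126 to 0.0362), though Hbb-bt alone had 9 UMIs in each library. Of the 579 control haemoglobin UMIs, 503 lay in 3 cells. Without the 3 highest cells of each library 76 control and 9 model UMIs were left, a ratio of 0.0948 (0.0418 to 0.190). Haemoglobin tells of red cells only, so white blood cells without red cells stay possible too. Organised lymphoid tissue left in the preparation stays possible: naive T cell genes had a median of 0.47 in T cells (−0.37 to 1.75; percentile 99.87), with Ccr7 at a ratio of 3.37, Lef1 at 1.90 and Tcf7, also a leading gene of lymphocyte cluster 12, at 0.773, and most of these genes were below their level in other classes. A true rise in B cells was not tested and stays open.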
